A study of Mus musculus with 21 samples.

How the data were processed

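RNA sequencing covered 3 ES cell libraries, and 3 control and 3 Dot1l KO libraries each in LIF and under Wnt3a and activin A. Thio-ChIP had 1 library with its input, and H3K79me2 ChIP had 1 library per treatment with its input. Groups and replicate numbers were taken from the sample titles in the labels. Per the labels' protocols, ES cells were kept on inactivated mouse embryonic fibroblasts, and the cells for H3K79me2 were grown without feeders. For Thio-ChIP, retinoic acid (500 nM) and 3-MB-PP1 (1 µM) were given together over 16 h to gather cells at G2/M, followed by 25 min of labelling without the inhibitor, per the labels' protocols.

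The deposited expression tables give FPKM per gene and library, computed by the authors, and in the KO tables the authors' p-value and q-value per gene with a status. Per the submitters' processing notes, STAR 2.5.4a, Cufflinks 2.2.1, Cuffdiff, Bowtie, Bowtie2 2.2.9, MACS 1.4.2, MACS2 2.1.1 and bcl2fastq 2.18 were used on the series, with no role given, and mm9 and GRCm38 are named as builds. The scaling between libraries, the annotation release and the filters are not given in the sources used here. FPKM divides by transcript length and library size, so a change in a few abundant genes shifts the others. Each table lists 53796 genes, of which 53616 matched the table of gene IDs and symbols, and 27 symbols that had been turned into dates were restored by gene ID. Of 37051 genes also in the GRCm38.p6 gene table by symbol, 99.8% overlapped its locus, so coordinates of genes are those of GRCm38.

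The deposited peak lists give a start, an end and the authors' score per peak, and what the score measures is not given in the sources used here. Peaks were called on 1 ChIP library each, and the names in the H3K79me2 lists name the input as the control, per the file contents. With the lists pooled, a peak ended beyond the last GRCm38 gene on 8 of 20 chromosomes. This argues against GRCm38 for at least 1 list, and the build of each list was not settled. Peaks and genes were therefore not joined. The planned analyses of Thio-ChIP peaks against gene starts and expression, of H3K79me2 over genes and Dot1l KO response, and the naming of genes at peaks were not run.

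The depth of the FPKM libraries is unknown. A rough relative depth came from the lowest values, where a library's steps can be compared: it ranged from 0.616 to 1.30 of KO replicate 1 in LIF and from 0.511 to 0.929 of KO replicate 1 under Wnt3a and activin A, but only 30.1% to 47.1% of the ratios lay within 0.1 on the log2 scale of their mode. Under Wnt3a and activin A the control libraries were thus the shallower ones. The precision of low genes is limited accordingly. The gene Mir6236 held 28.6% of summed FPKM in KO replicate 3 in LIF and 5.25% to 8.31% in the other libraries of that table. Pearson correlations of log2 values were 0.931 to 0.959 within groups and 0.925 to 0.958 between groups in LIF, and 0.943 to 0.955 within and 0.914 to 0.925 between groups under Wnt3a and activin A. No pair of libraries held identical values.

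Each table was tested alone in limma 3.58.1 (R 4.3.3) with a trend, on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 6 libraries. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are KO minus control on that scale, which understates changes of low genes. The difference between conditions was an interaction term over all 12 libraries for genes tested in both tables. Overlap of calls was tested with Fisher's exact test. A total of 26 gene lists were fixed, along with the tests and alternatives, before the data were examined. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over 48 tests, and again with an estimated correlation, with which none of the 18 calls held (lowest adjusted p = 0.145). A minimum of 3 measured members for camera, which left out the 2-cell-like and the Hox and Meis lists, was chosen after seeing the data.

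Genes were named by a rule: Dot1l, and per comparison the 10 higher and 10 lower genes with the largest change among those past the threshold, with a mean of at least 1 FPKM in a group, groups that do not overlap and a symbol that is not a clone or predicted name. Up to 4 members past the threshold with the largest change were named per list, in the text for lists that passed and for general pluripotency under Wnt3a and activin A. The interaction part took 5 genes per direction, with groups not overlapping in at least 1 condition. That last condition, and the limit to lists that passed, were chosen after seeing the data. Some genes that the rule names are not reported here. Chance gives non-overlapping groups in 10% of genes with 3 libraries against 3. The annotation lists several genes at some loci, and where genes overlap their FPKM values can take reads from each other: 15 genes share the locus of Sox2, 16 that of Mirg, 12 that of Cd34, 9 that of Fgf1 and 8 that of Tagln, themselves included.

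The fits were tested on simulated data with 200 changed genes, drawn from those with a mean log2 value above 2. Errors were normal and independent between genes, with no trend in span or level. The rates below need not hold for lower genes. They also need not hold under Wnt3a and activin A, where far more genes passed along such a trend. At a log2 change of 0.5, 1 and 2, recovery was 44.8%, 79.1% and 95.5% in LIF, 40.3%, 74.6% and 97.0% under Wnt3a and activin A, and 31.3%, 79.1% and 95.5% for the interaction, with 3.31%, 2.76% and 6.80% false calls. Peak overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and matched bedtools 2.31.1 on 300 simulated intervals. Coordinates are printed counting from 1. Random placements kept each Thio-ChIP peak on its chromosome, from 3 Mb on, 100 times.

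Alternatives were a pseudocount of 0.1 or 0.5, no filter on low values or a mean of at least 5 FPKM, quantile normalization, median-of-ratios rescaling, limma without a trend, a minimum log2 fold change of 1, the authors' deposited q-value, the replicate number as a block, and each library left out in turn. Peak alternatives were a larger minimum overlap, the top-scoring part of each list, equal numbers of peaks, merging within 1 kb and autosomes only. Removal of a spline trend (5 degrees of freedom) with gene span, or with span and level, rescaled list tests, the overlap within 10 classes of expression level and the random placements were added after seeing the data.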

Results

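The series joins 3 kinds of measurement in mouse embryonic stem (ES) cells, the self-renewing cells derived from the early embryo. Chromatin immunoprecipitation sequencing (ChIP-seq) was made in cells whose Cdk1, the main mitotic cyclin-dependent kinase, carries an analog-sensitive form that the inhibitor 3-MB-PP1 blocks. It comprised 1 Thio-ChIP library, which recovers DNA bound by proteins that Cdk1 has labelled with thiophosphate, and H3K79me2 libraries after 4 days of 1 µM 3-MB-PP1 or of the solvent DMSO, 1 library each. H3K79me2 is the methylation mark on histone H3 that the enzyme Dot1l deposits. RNA sequencing covered 3 libraries of ES cells, and 3 control and 3 Dot1l knockout (KO) libraries in each of 2 conditions. The first was medium with leukemia inhibitory factor (LIF), which keeps ES cells undifferentiated, and the second was 24 h of differentiation with 50 ng/ml Wnt3a and 10 ng/ml activin A. Expression values were FPKM, so the sequencing depth of each library is unknown. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

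The first comparison asked what loss of Dot1l changes in undifferentiated cells. Dot1l (ENSMUSG00000061589, chromosome 10, 80755101 to 80795461 of GRCm38) was at 21.2, 20.6 and 24.6 FPKM in the control libraries and at 11.2, 8.90 and 10.8 FPKM in the KO libraries. Its log2 fold change was -1.04 (SE 0.11, limma adjusted p = 0.0178), so its transcript was lower but still present in every library labelled KO. The labels do not say whether the KO cells are a clone or a pool, so the effects below are those of the cells labelled KO and may be of partial loss. The titles of the control libraries name a guide RNA (sgRNA). Transcript level does not show how much Dot1l protein or activity remained, which was not measured. Thbs1, which encodes the matrix protein thrombospondin 1, rose from 7.43 ± 0.403 to 17.7 ± 0.359 FPKM (SD, n = 3). Ntn1, a secreted guidance cue, fell from 13.8 ± 0.788 to 4.37 ± 0.294 FPKM, and Cntfr, the receptor of ciliary neurotrophic factor, fell from 14.8 ± 1.63 to 5.00 ± 0.454 FPKM. Mras, a small GTPase, fell from 27.6 ± 2.00 to 8.98 ± 2.29 FPKM.

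Other genes with large increases in LIF were Usp17le (log2 fold change 1.64), Slc4a5 (1.55), Adamtsl4 (1.34), Bcas1 (from 4.51 to 11.5 FPKM), Pdlim3 (1.17), Rhox13 (1.15), Cd34 (1.13) and the germ cell transcription factor gene Sohlh2 (1.11). The other large decreases were in Polr3gl (log2 fold change -1.24), Lrr1 (-1.10), Fgf1 (-1.05), Slc4a2 (-1.02), the mitochondrial pyruvate carrier gene Mpc1 (-0.99) and Slc25a12 (-0.98). Adjusted p-values of these 14 genes and of Thbs1, Ntn1, Cntfr and Mras lay between 0.00685 and 0.0465. In total 580 of 13153 genes passed an adjusted p of 0.05 in limma, 126 higher and 454 lower in the KO. The share of higher genes was 21.7%, against 34.6% after median-of-ratios rescaling and 47.2% after quantile normalization. It was 53.5% with the trend in span and level removed, so the excess of lower genes depended on the scaling. The count rested on all 6 libraries: it was 20, 12 and 14 without KO replicates 1, 2 and 3, and 40, 1 and 18 without control replicates 1, 2 and 3. It was 259 with no filter on low values, 269 with quantile normalization, 236 in limma without a trend, and 331 after a trend with gene span and level was removed. With the replicate number as a block in limma 0 genes passed (2733 at an unadjusted p under 0.05), although the labels do not say that the numbers pair the libraries.

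Naive pluripotency genes were lower in the KO in LIF. Of 16 measured members, 7 fell and 1 rose, and adjusted over the list alone 14 were lower and 1 higher. Nr0b1 fell from 70.8 ± 3.51 to 36.9 ± 1.91 FPKM (SD, n = 3), Gbx2 from 31.4 ± 2.19 to 17.3 ± 1.74 FPKM and Klf5 from 74.1 ± 3.79 to 43.9 ± 1.27 FPKM, while Dppa3, a gene shared with germ cells, rose from 42.4 ± 3.04 to 70.1 ± 5.62 FPKM. The list had a median log2 fold change of -0.37 and an adjusted p of 2.95e-06 in camera (adjusted p = 0.199 with an estimated correlation). Among general pluripotency genes, 5 of 12 fell and 9 were lower adjusted over the list alone, with log2 fold changes of -0.47 for Trim71, -0.43 for Sox2, -0.33 for Utf1 and -0.26 for Tdgf1. The median was -0.24 (camera adjusted p = 0.000688; adjusted p = 0.177 with an estimated correlation). In the same libraries fibroblast and feeder markers had a median of 0.53, with 5 of 8 higher adjusted over the list alone, and mitochondrially encoded transcripts one of 0.55, with 6 of 9 higher, so the change was not confined to pluripotency genes.

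Germline genes were higher in the KO in LIF. Mael, which acts in the piRNA pathway, rose from 17.1 ± 1.80 to 34.4 ± 2.51 FPKM (SD, n = 3), and the germ cell RNA-binding gene Dazl rose from 1.97 ± 0.0557 to 4.00 ± 0.149 FPKM. Tuba3a and Ddx4 rose with log2 fold changes of 0.77 and 0.35. In this list 4 of 14 measured members passed over all genes, and 12 were higher adjusted over the list alone. Its median was 0.56 (camera adjusted p = 4.46e-13; adjusted p = 0.145 with an estimated correlation). In these libraries fibroblast markers had a median of 0.53, with 2 of 8 higher over all genes (camera adjusted p = 0.177 with an estimated correlation). Mitochondrially encoded transcripts, not tested as a list, had one of 0.55, with 6 of 9 higher. A median of this size is thus not specific to germline genes.

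The endoderm and trophoblast lists had positive medians in LIF, with few members past the threshold in the endoderm lists. As for the germline genes, other medians in the same libraries stand beside these. Fibroblast markers had 0.53, with 2 of 8 higher over all genes, and mitochondrially encoded transcripts 0.55, with 6 of 9 higher. Extraembryonic endoderm genes had a median of 0.33 (camera adjusted p = 1.23e-07; adjusted p = 0.151 with an estimated correlation), with 2 of 12 members past the threshold, the basement membrane genes Col4a1 (0.46) and Lama1 (0.35), and 4 adjusted over the list alone. Definitive endoderm genes had a median of 0.24 (camera adjusted p = 0.000611; adjusted p = 0.177 with an estimated correlation), with 1 of 9 members past the threshold over all genes and adjusted over the list alone, the tight junction gene Cldn6 (0.27). Trophoblast genes had a median of 0.46 (camera adjusted p = 0.00628; adjusted p = 0.177 with an estimated correlation). In that list the keratin genes Krt7 (0.89), Krt18 (0.69) and Krt8 (0.53), which are not specific to trophoblast, and 1 further member rose, while Tead4 (-0.58) fell. Adjusted over the list alone, 5 of its 11 members were higher and 2 lower. Its call ended with quantile normalization (adjusted p = 0.0515) and without control replicate 3 (adjusted p = 0.117).

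Nodal and activin targets had a median of 0.38 in LIF (camera adjusted p = 0.0116; adjusted p = 0.312 with an estimated correlation). Id3 (0.66) and the Nodal antagonist gene Lefty1 (0.51) rose and Smad7 (-0.56) fell. In all 4 of 9 members rose and 2 fell, or 5 and 3 adjusted over the list alone. Fibroblast and feeder markers, the list for cells carried over from the feeder layer, had a median of 0.53 (camera adjusted p = 3.58e-07; adjusted p = 0.177 with an estimated correlation). Of its 8 measured members Acta2 rose from 5.50 to 10.7 FPKM and Timp3 from 2.43 ± 0.254 to 4.24 ± 0.236 FPKM (SD, n = 3), and 5 were higher adjusted over the list alone.

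Ribosomal protein genes and G1/S genes had small negative medians in LIF. The ribosomal protein genes had a median of -0.18 (camera adjusted p = 0.00119; adjusted p = 0.418 with an estimated correlation), and 2 of 16 fell, among them Rps14 (-0.25), against 14 adjusted over the list alone. The median was -0.02 with quantile normalization (adjusted p = 0.714) and -0.03 with the trend in span and level removed (camera adjusted p = 0.543). The ribosomal call held with median-of-ratios rescaling (median -0.13, camera adjusted p = 0.00451). It also held with the trend in span alone removed (median -0.11, camera adjusted p = 0.0410). The G1/S genes had a median of -0.11 (camera adjusted p = 0.0192; adjusted p = 0.466 with an estimated correlation), and 3 of 17, E2f1 (-0.50), Cdk4 (-0.33) and Pcna (-0.24), fell, against 7 adjusted over the list alone. That call ended with median-of-ratios rescaling (adjusted p = 0.0564), with quantile normalization (adjusted p = 0.316) and without KO replicate 3 (adjusted p = 0.0589). It also ended with the trend in gene span removed (camera adjusted p = 0.103) and with span and level removed together (0.433).

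For orientation, levels in control cells were set side by side between the conditions, with no test because the tables were scaled separately. All 13 primitive streak and mesendoderm genes were at a higher level under Wnt3a and activin A, with a median of 21.1 FPKM against 0.235 FPKM in LIF. All 16 naive pluripotency genes were at a lower level, with a median of 1.92 against 53.8 FPKM. Of 12 general pluripotency genes, 2 were at a higher level under differentiation.

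The second comparison asked what loss of Dot1l changes during differentiation with Wnt3a and activin A. Lhx1, a homeobox gene of the primitive streak (ENSMUSG00000018698, chromosome 11, 84517975 to 84525534 of GRCm38), rose from 7.62 ± 0.816 to 98.5 ± 7.47 FPKM (SD, n = 3) in the KO. Mesp1, an early mesoderm transcription factor gene, rose from 0.975 ± 0.0716 to 12.3 ± 0.687 FPKM, and Cer1, which encodes a secreted antagonist of Nodal, BMP and Wnt signals, rose from 7.35 ± 0.644 to 42.6 ± 0.516 FPKM. Sfn, which encodes the 14-3-3 protein sigma, fell from 153 ± 6.27 to 30.0 ± 1.68 FPKM, and the growth factor gene Gdf3 fell from 9.86 ± 0.483 to 1.59 ± 0.340 FPKM. Dot1l itself was at 18.5, 17.7 and 19.1 FPKM in the control libraries and at 13.5, 12.9 and 14.7 FPKM in the KO libraries. Its log2 fold change was -0.40 (SE 0.07, limma adjusted p = 0.00462), so the transcript fell by 25.7%, which does not measure loss of the enzyme.

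**Figure D1:**
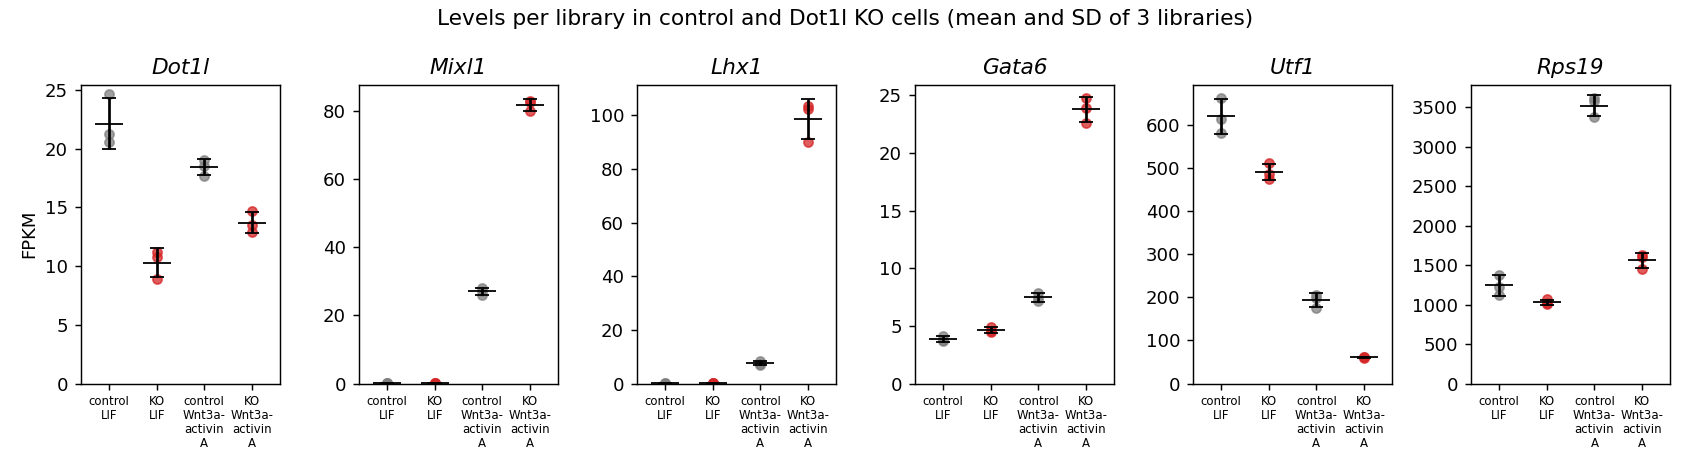
Levels in FPKM (vertical axis) of 6 genes in control (grey) and Dot1l KO (red) libraries in LIF and under Wnt3a and activin A, with each point a library and bars the mean and SD of 3 libraries. Dot1l was lower in the KO libraries of each condition, and Lhx1 stood at 98.5 FPKM in the KO against 7.62 FPKM in the control under Wnt3a and activin A.

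The other genes with the largest increases under Wnt3a and activin A were Greb1l (log2 fold change 3.86), Sept2 (3.38), Ints5 (2.96), Fam107b (2.55), the Wnt antagonist gene Frzb (2.52), Zc3h11a (2.38) and Amot (2.31). Greb1l, Ints5, Fam107b and Zc3h11a share their locus with 4, 7, 4 and 4 listed genes, themselves included, so their values are uncertain. The Zc3h11a call ended without any 1 of 5 libraries, KO replicate 1 (adjusted p = 0.0710), 2 (0.0754) or 3 (0.0650) or control replicate 2 (0.0602) or 3 (0.0819). It also ended with no filter on low values (limma adjusted p = 0.0603), and the Ints5 call ended without KO replicate 2 (adjusted p = 0.0511). The other large decreases were in Rpgrip1 (-4.53), the short RNA Rmrp (-3.87), the noncoding RNA Platr10 (-2.17), the stress-response gene Gadd45b (-1.95), Fgfbp1 (-1.93), Abhd11os (-1.83), Yipf2 (-1.80) and Eif4ebp3 (-1.79). In total 6273 of 12770 genes passed an adjusted p of 0.05 in limma, 2500 higher and 3773 lower. The excess of lower genes depended on the scaling, with 2746 higher and 2889 lower after quantile normalization, and 2385 and 2465 with the trend in span and level removed. With a log2 fold change of at least 1 in size as well, 809 genes passed.

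Log2 fold changes under Wnt3a and activin A followed gene span and level. The 10% of genes with the shortest span, below 3.19 kb, had a median of -0.51, and the 10% with the longest, above 109 kb, had a median of 0.29. Across genes, which are not independent replicates, Spearman's rho was 0.429 with span and -0.330 with mean level, against 0.0702 and -0.242 in LIF. Summed FPKM was 759255 to 792381 in the KO libraries and 1087970 to 1144370 in the controls under Wnt3a and activin A. In tables scaled separately it was 835737 to 895128 in LIF, apart from KO replicate 3 (1079780), and 666191 to 707882 in ES cells. The controls under Wnt3a and activin A thus had the highest sums, while the KO sums of that condition lay between those of ES cells and of LIF. Because the tables were scaled separately, which group carries the shift cannot be told. After removal of the trend with span and level, a step chosen after seeing the data, 3726 of the 6028 calls that could be tested remained in the same direction.

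Primitive streak and mesendoderm genes were higher in the KO under Wnt3a and activin A. Of 13 measured members, 11 rose and 1 fell, the same counts as adjusted over the list alone. Lhx1, Mesp1, Cer1 and Mixl1 led the list, and Mixl1 rose from 27.1 ± 1.08 to 81.8 ± 1.67 FPKM (SD, n = 3). The median was 0.77 (camera adjusted p = 2.42e-06; adjusted p = 0.177 with an estimated correlation), and 1.29 after the trend with span and level was removed. Mesoderm genes had a median of 0.87 (camera adjusted p = 6.21e-05; adjusted p = 0.151 with an estimated correlation), with 8 of 10 members higher over all genes and adjusted over the list alone. Besides Mesp1, Msgn1 (2.18), the bone morphogenetic protein gene Bmp4 (1.23) and the growth factor receptor gene Pdgfra (1.10) rose.

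Endoderm genes were also higher in the KO under Wnt3a and activin A, in lists that share members with each other and with those above. Cer1 and Foxa2 are in the primitive streak and definitive endoderm lists, and Mesp1 and Tbx6 in the primitive streak and mesoderm lists. Gata6 is in both endoderm lists, and Gata4 and Pdgfra are in the mesoderm and extraembryonic endoderm lists. The lists are thus not separate evidence. Definitive endoderm genes had a median of 1.07 (camera adjusted p = 0.00846; adjusted p = 0.418 with an estimated correlation), and 8 of 12 members rose and 3 fell, as adjusted over the list alone. Besides Cer1, the chemokine receptor gene Cxcr4 (1.81) and the transcription factor genes Gata6 (1.55) and Sox17 (1.33) rose. Extraembryonic endoderm genes had a median of 0.58 (camera adjusted p = 1.46e-05; adjusted p = 0.151 with an estimated correlation). In this list 9 of 14 members rose, or 10 adjusted over the list alone, led by Gata6, Pdgfra, Col4a1 (1.00) and Dab2 (0.94). In the same libraries fibroblast and feeder markers had a median of 0.75 (camera adjusted p = 0.128), with 5 of 8 higher and 1 lower, and Tagln at -1.77. Mitochondrially encoded transcripts had a median of 0.25, with 4 of 9 higher, so rises were not confined to mesoderm and endoderm genes.

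Wnt pathway targets had a median of 0.37 under Wnt3a and activin A (camera adjusted p = 0.000345; adjusted p = 0.151 with an estimated correlation). Of 13 members 10 rose, or 11 adjusted over the list alone, with log2 fold changes of 1.04 for Lef1, 1.03 for Cdx1, 0.78 for Sp5 and 0.60 for Sp8. The Sp8 call ended with quantile normalization (adjusted p = 0.0607), with no filter on low values (0.0567) and without KO replicate 2 (adjusted p = 0.0715), control replicate 1 (0.0653) or control replicate 2 (0.0628). Chromatin modifier genes had a median of 0.29 (camera adjusted p = 0.00846; adjusted p = 0.466 with an estimated correlation). The Polycomb gene Suz12 (1.32), the H3K27 demethylase gene Kdm6a (1.30) and the H3K4 methyltransferase genes Kmt2d (1.00) and Kmt2a (0.96) led the 14 of 29 members that rose, and 6 fell, against 15 and 6 adjusted over the list alone. That call ended when the trend with gene span was removed (adjusted p = 0.269) and when span and level were removed together (adjusted p = 0.0787). It held with quantile normalization (median 0.33, camera adjusted p = 0.000646) and with median-of-ratios rescaling (median 0.35, camera adjusted p = 0.00699).

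Imprinted genes went both ways under Wnt3a and activin A. Peg3 (1.70) and Mest (1.21) rose, and the noncoding RNAs Mirg (-1.28) and Meg3 (-1.24) fell. Of 15 members 12 rose and 3 fell, as adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00846; adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes fell under Wnt3a and activin A with the authors' scaling, in 16 of 16 members over all genes and adjusted over the list alone. Their median level in control cells was 3358 FPKM in this condition and 1840 FPKM in LIF, in tables scaled separately. Rps19 fell from 3519.7 ± 130.6 to 1559.5 ± 97.1 FPKM (SD, n = 3), a log2 fold change of -1.18, and log2 fold changes were -1.12 for Rplp1 and -1.01 for Rpl18. The median was -0.88 (camera adjusted p = 1.15e-07; adjusted p = 0.291 with an estimated correlation). It was -0.11 with quantile normalization (adjusted p = 0.171), where Rplp1 (-0.04) and Rpl18 (-0.10) no longer passed, and -0.09 after the trend with span and level was removed (adjusted p = 0.182). The call of the list held with median-of-ratios rescaling (median -0.82, camera adjusted p = 2.25e-08). It also held with the trend in span alone removed (median -0.50, camera adjusted p = 7.16e-07). General pluripotency genes as a list did not pass under Wnt3a and activin A (median -0.17, camera adjusted p = 0.252), although 6 of 11 members fell, led by Dppa4 (-1.67), Utf1 (-1.65) and Dppa5a (-1.01), and 2 rose, including Sall4 (0.86).

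**Figure D2:**
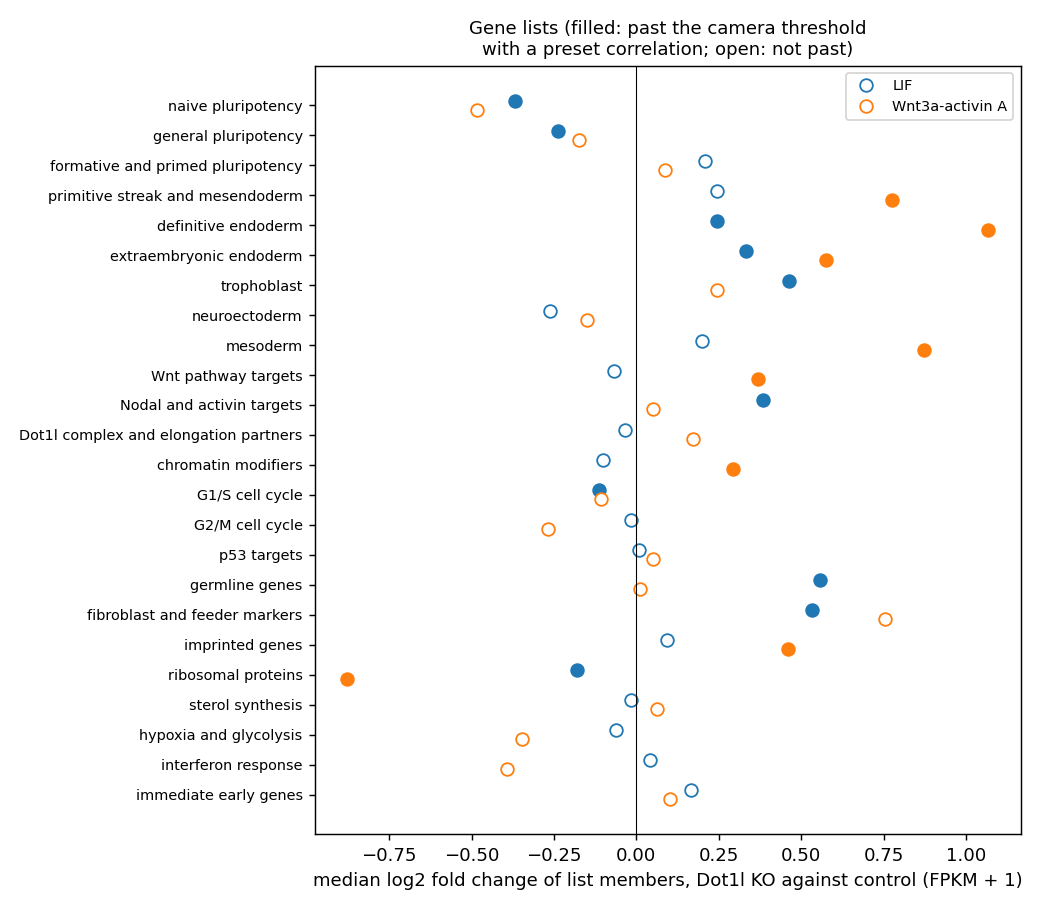
Median log2 fold change of list members (horizontal axis, on the FPKM + 1 scale) in Dot1l KO against control for each fixed gene list in LIF (blue) and under Wnt3a and activin A (orange). Filled points mark lists past the camera threshold with the preset correlation, none of which passed with an estimated correlation; the primitive streak list had a median of 0.77 under Wnt3a and activin A.

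The difference between the conditions was tested in a joint fit over the 12 libraries. Ntn1, which fell in LIF (-1.46), had a log2 fold change of 1.31 under Wnt3a and activin A, a difference of 2.77 (SE 0.11, limma adjusted p = 9.83e-07). The largest positive differences were otherwise in Greb1l (4.37), Ints5 (3.58), Sept2 (3.55) and Fam107b (2.96). Tagln, a smooth muscle and fibroblast gene, had log2 fold changes of 0.54 in LIF and -1.77 under Wnt3a and activin A, a difference of -2.31. Acta1 (-2.86), Rpgrip1 (-4.60), Platr10 (-2.19) and the small nucleolar RNA Snord83b (-10.48, SE 2.66) had the other large negative differences, and the value of Snord83b is uncertain because FPKM is unreliable for such short RNAs. In total 4513 of 11783 genes tested in both conditions differed, 2071 more positive and 2442 more negative under Wnt3a and activin A. The balance turned to 1980 and 1782 with quantile normalization, and to 1666 and 1582 with the trend in span and level removed. With a difference of at least 1 in size as well, 701 passed.

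Genes lower in the KO overlapped between the conditions. Of 437 genes lower in LIF and 3678 lower under Wnt3a and activin A, 252 were shared, against 136 for independent lists. The odds ratio was 3.15 (95% interval 2.58 to 3.84, two-sided Fisher's exact test p = 2.93e-31), and 1.53 within 10 classes of expression level (p = 0.000148), a comparison chosen after seeing the data. Of 101 genes higher in LIF and 2344 higher under Wnt3a and activin A, 24 were shared against 20.1 for independent lists (odds ratio 1.26, 95% interval 0.759 to 2.02, Fisher's exact test p = 0.318). A further 75 genes passed in opposite directions. Across genes, which are not independent replicates, log2 fold changes correlated with a Pearson r of 0.110 and a Spearman rho of 0.218.

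The ES cell libraries described the transcriptome of cells in LIF without a comparison. Pluripotency genes were highly expressed, with Dppa5a at 1298 ± 138, Pou5f1 at 929 ± 32.1, Tdgf1 at 455 ± 26.5 and Utf1 at 201 ± 10.2 FPKM (SD, n = 3), and Nanog at 166 ± 5.12 FPKM. The 16 naive pluripotency genes all had a mean of at least 1 FPKM, with a median of 36.4 FPKM. Cdk1 was at 277 ± 38.4 FPKM, next to Ube2c at 389 ± 7.50, Top2a at 380.3 ± 16.6 and Cdc20 at 186 ± 16.4 FPKM among G2/M genes, and Dot1l was at 13.7 ± 0.802 FPKM. Fibroblast and feeder markers were present as well, with Tagln at 121 ± 19.6, Acta2 at 27.4 ± 3.81, Thy1 at 10.4 ± 1.53 and Col1a1 at 8.82 ± 2.56 FPKM. In total 13115 genes had a mean of at least 1 FPKM.

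The H3K79me2 libraries addressed what inhibition of Cdk1 does to this mark, with 1 library per condition and therefore no replicate check. The list for 3-MB-PP1 held 22352 peaks covering 132 Mb, and the list for DMSO held 13437 peaks covering 59.9 Mb, a ratio of covered length of 2.21. Of the DMSO peaks, 13010 shared at least 1 bp with a 3-MB-PP1 peak (96.8%, 95% Wilson interval 96.5 to 97.1, counting error only). Of the 3-MB-PP1 peaks, 8382 met a DMSO peak (37.5%, 36.9 to 38.1), and the 13970 that met none had a median width of 1.35 kb and covered 31.3 Mb. Of the 8382, 2379 each joined 2 or more DMSO peaks.

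Peaks wider than 20 kb numbered 1467 with 3-MB-PP1 and 484 with DMSO. The widest peak of each list lay on chromosome 10, from 66517442 to 66697028 (179.6 kb) with 3-MB-PP1 and from 66547408 to 66693808 (146 kb) with DMSO. These are positions as the peak lists give them, whose build was not settled list by list. With the 13437 top-scoring peaks of each list, the score being the authors' value for each peak, the ratio of covered length was 1.97. The depth of these libraries is unknown, and a difference in depth or background between them would also change the number and width of peaks.

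**Figure D3:**
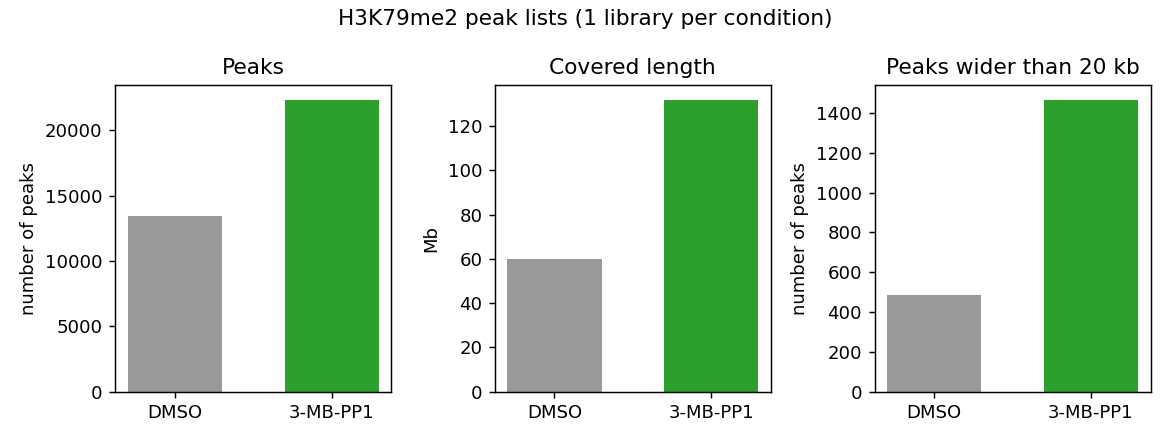
Number of H3K79me2 peaks, covered length in Mb and number of peaks wider than 20 kb in the DMSO (grey) and 3-MB-PP1 (green) lists, with 1 library per condition and no error bars. The 3-MB-PP1 list covered 132 Mb and the DMSO list 59.9 Mb.

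The Thio-ChIP library addressed where in the genome substrates of Cdk1 lie. Its list held 7924 peaks covering 13.7 Mb, with a median width of 1.61 kb. The highest-scoring peak lay on chromosome 17 from 39979444 to 39986339, with a score of 3100 against 1060 for the next, on chromosome 17 from 34254885 to 34260461. Whether repeated sequence raised the highest score was not tested, so the score does not rank this peak as a site of Cdk1 substrates. Of the Thio-ChIP peaks, 2852 met an H3K79me2 peak of the DMSO list by at least 1 bp (36.0%, 95% Wilson interval 34.9 to 37.1, counting error only), against 2.73% to 4.18% in 100 random placements, a reference added after seeing the data. With the 3-MB-PP1 list 3522 met a peak (44.4%), against 6.30% to 8.08%. When at least 50% of the Thio-ChIP peak had to be covered, 679 did so with the DMSO list (8.57%). The placements took no account of which sequence can be mapped or of where genes lie. Whether the excess over them is specific to H3K79me2 was therefore not tested. The overlap assumes that the lists use the same build, which was not checked for each list. The lists also come from cells treated differently. The Thio-ChIP cells were given retinoic acid and gathered at G2/M, and the labels name neither step for the H3K79me2 cells.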

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

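Each gene and list in this part stands here because its Dot1l KO effect differed between LIF and Wnt3a with activin A in the test of the difference itself. The removal of trends with gene span and level, the look at which splits kept the genotypes apart, and the splits of the lists within a condition, were chosen after the results were seen. Values are log2 differences, the KO effect under Wnt3a and activin A minus that in LIF. In total 4513 of 11783 genes differed. Wnt pathway targets had a median difference of 0.42 (camera adjusted p = 0.00737; adjusted p = 0.511 with an estimated correlation), chromatin modifiers one of 0.37 (adjusted p = 0.00185; adjusted p = 0.511 with an estimated correlation) and ribosomal proteins one of -0.71 (adjusted p = 4.61e-10; adjusted p = 0.416 with an estimated correlation). The other lists did not pass, among them mesoderm (adjusted p = 0.186), definitive endoderm (0.490), extraembryonic endoderm (0.111) and primitive streak genes (0.404, with only 3 members measured in both conditions).

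Named members of the mesoderm and endoderm lists went in either direction, Bmp4 (2.29), Gata6 (1.34), Sox17 (0.90), Pdgfra (0.82), Col4a1 (0.54) and Lama1 (0.39) upward and Cldn6 (-0.87) downward. Wnt targets and chromatin modifiers with a more positive effect were Lef1 (1.79), Sp5 (1.06), Cdx1 (1.0053), Kdm6a (1.10), Kmt2d (1.08), Suz12 (1.05) and Kmt2a (0.82). Pluripotency genes differed in either direction: Sall4 (1.16), Klf5 (1.10), Sox2 (0.57), Trim71 (0.38), Dppa3 (-1.48), Dppa4 (-1.51), Dppa5a (-0.89) and Utf1 (-1.32). Ribosomal protein genes with a more negative effect were Rps14 (-0.55), Rpl18 (-0.81), Rplp1 (-0.81) and Rps19 (-0.91). Members of the trophoblast list were Krt7 (-0.65), Krt8 (-0.99), Krt18 (-1.47) and Tead4 (0.81), and members of the fibroblast list Acta2 (-0.77) and Tagln (-2.31). Imprinted genes were Peg3 (1.48), Mest (1.10), Meg3 (-0.66) and Mirg (-1.11). Other genes with a more positive effect were Greb1l (4.37), Ints5 (3.58), Sept2 (3.55), Fam107b (2.96), Ntn1 (2.77), Zc3h11a (2.30), Mras (1.92), Slc25a12 (1.79), Amot (1.78), Polr3gl (1.47), Slc4a2 (1.12), Cntfr (0.86) and Dot1l (0.63). Other genes with a more negative effect were Cdk4 (-0.33), Thbs1 (-0.40), Id3 (-0.61), Mael (-0.86), Bcas1 (-1.02), Lefty1 (-1.09), Gadd45b (-1.54), Gdf3 (-1.68), Yipf2 (-1.69), Slc4a5 (-1.72), Abhd11os (-1.88), Sfn (-1.89), Pdlim3 (-2.02), Adamtsl4 (-2.03), Fgfbp1 (-2.05), Platr10 (-2.19), Acta1 (-2.86), Rpgrip1 (-4.60) and Snord83b (-10.48).

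Of 100 splits of the 12 libraries, 3 gave as many differing genes as the real split, and the highest other count was 4580. The 7 drawn splits that kept the genotypes apart under Wnt3a and activin A held all 3, and the others gave at most 2 genes. The share of 3 in 100 thus rests on how few drawn splits kept these genotypes apart. It cannot exclude chance for a difference between the conditions. Splits that shuffled only the LIF libraries gave counts as large, so the count itself carries the KO effect under Wnt3a and activin A and says little of the LIF libraries. For LIF alone the real split gave 580 genes and the highest of the others 5, and under Wnt3a and activin A these were 6273 and 3. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For the gene lists of both conditions together, 1 of 100 splits, the real one, gave as many lists past the threshold, 18 against at most 15 in the others. This argues against chance, without excluding it, and only for the pooled count: splits that kept the genotypes apart in LIF alone gave up to 15 lists and those that kept them apart under Wnt3a and activin A alone up to 13. Within LIF the real split gave 10 lists and the highest other 2, and under Wnt3a and activin A 8 and 4. In each condition 1 of 10 splits, the real one, gave as many lists, and 10 splits are too few for a share under 0.05.

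Under Wnt3a and activin A, genes with a long span were higher and abundant genes lower in the KO, and removing this trend ended the calls of the ribosomal protein and chromatin modifier lists. The fitted trend as the whole cause of the calls is argued against by the 59.4% of calls that remained in the same direction once it was removed. Among calls that could be tested this share was 61.8%. The trend is argued against for the primitive streak list as well, since it ran against the list's change. The median of that list rose from 0.77 to 1.29 with the trend removed. Calls left after this removal cannot speak on a bias that the fitted trend does not describe. With the trend in span and level removed the ribosomal protein list lost its call. Its median moved from -0.88 to -0.09, as that removal takes out a shift shared by abundant genes. The ribosomal call held with the trend in span alone removed (median -0.50) and with median-of-ratios rescaling (median -0.82). A difference in RNA quality or library preparation that coincides with genotype remains possible: libraries of a group differed along span by a correlation of up to 0.118, against 0.429 between the groups, and a difference shared by all 3 libraries of a group cannot be told apart from the genotype. An effect of Dot1l on long or abundant genes stays open as well and was not tested apart from these.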

How the results depend on the processing

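The trend removal, rescaled list tests and overlap within classes of expression were chosen after the data were seen. In LIF, the 580 genes became 0 with the replicate number as a block in limma (2733 at an unadjusted p under 0.05), 259 with no filter on low values, 269 with quantile normalization, 236 in limma without a trend, 331 with the trend in span and level removed, 29 with a log2 fold change of at least 1, and 1007 by the q-value of the authors' deposited table, of which 391 were shared. Leaving out 1 library gave 1 to 40. With the block 5594 genes passed under Wnt3a and activin A and 3913 for the interaction. The labels do not say that replicate numbers pair the libraries. Correlations of same-numbered deviations lay between -0.01 and 0.06, and of differently numbered ones between -0.08 and 0.07. This gives no sign of pairing but cannot exclude it, so whether the loss in LIF is a weaker effect cannot be told. Under Wnt3a and activin A the count was 809, and for the interaction 701, with a log2 size of at least 1, and 5307 to 5595 and 3982 to 4236 without 1 library. Stricter size limits test the same genes and keep fewer; the cause of the other losses in LIF was not tested. With an estimated correlation 0 of 18 lists passed in camera. At an adjusted p of 0.01 the overlap of lower genes had an odds ratio of 0, since only 2 such genes were left in LIF. Cdk4 under Wnt3a and activin A turned from -0.66 to 0.0227 with quantile normalization and 0.13 with the trend in span and level removed.

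Of 49 named genes in LIF, between 0 and 8 still passed without 1 library and 24 with no filter, with no change of direction; of 52 under Wnt3a and activin A at least 49 did without 1 library, and all 10 of the interaction did. For H3K79me2, 94.5% of DMSO and 21.3% of 3-MB-PP1 peaks were shared when 50% had to be covered, 97.2% and 49.7% in the top 50% by score with a length ratio of 2.34, and 94.3% and 59.6% with equal numbers of peaks with a ratio of 1.97. Merging within 1 kb moved nothing, as the smallest gap was 1161 bp. For Thio-ChIP, 8.57% met a DMSO peak and 18.5% a 3-MB-PP1 peak with 50% covered, and 44.4% a 3-MB-PP1 peak by at least 1 bp. The count of expressed genes in ES cells lay between 9200 and 19540 over minimum levels and between 13011 and 13090 without 1 library. Not run were alternatives that join peaks to genes, a floor for tables with 1 value per group, and the authors' q-value for the interaction. Unknown depth limits calls of low genes.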

Other observations

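The random placements, the trend removal, the classes of mitochondrial, histone and Rhox genes, the test of markers low in the controls, and the comparison with the differentiation change were chosen after the data were seen. The patterns had been seen before their tests were set, and the rules by which the tests of carry-over and of peak calling are read were completed after their values were known. Lists other than those described above did not pass in camera. Naive pluripotency genes under Wnt3a and activin A had a median of -0.48 (adjusted p = 0.704), and germline genes 0.01 (adjusted p = 0.820). Formative and primed genes had medians of 0.21 in LIF (adjusted p = 0.0736) and 0.09 under Wnt3a and activin A (adjusted p = 0.369), neuroectoderm genes -0.26 (0.367) and -0.15 (0.780). Mesoderm and primitive streak genes in LIF had medians of 0.20 (adjusted p = 0.114) and 0.24 (adjusted p = 0.310), and Wnt targets -0.07 (adjusted p = 0.704). Trophoblast genes, Nodal and activin targets, and fibroblast markers under Wnt3a and activin A had medians of 0.24 (0.294), 0.05 (0.538) and 0.75 (0.128).

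G2/M genes had medians of -0.02 in LIF (adjusted p = 0.999) and -0.27 under Wnt3a and activin A (adjusted p = 0.271), where 10 of 16 members fell and 4 rose, and G1/S genes under Wnt3a and activin A had -0.11. p53 targets had 0.01 in LIF and 0.05 under Wnt3a and activin A (adjusted p = 0.271 and 0.939), Dot1l partners -0.03 and 0.17 (0.820 and 0.294), and sterol synthesis genes -0.01 and 0.06 (0.483 and 0.820). Glycolysis genes had -0.06 and -0.35 (0.905 and 0.154), interferon genes 0.04 and -0.39 (0.371 in LIF) and immediate early genes 0.16 and 0.10 (0.114 and 0.780). Imprinted genes and chromatin modifiers in LIF had 0.09 (0.0887) and -0.10 (0.310). In ES cells 9 of 15 listed genes of the 2-cell-like list and 3 of 18 Hox and Meis genes had a mean of at least 1 FPKM. Of 9 mitochondrially encoded transcripts, 6 rose in LIF (median 0.55) and 4 under Wnt3a and activin A (median 0.25). Of 5 Rhox genes, which are expressed in germ cells and placenta, 1 rose in LIF (median 0.59). Histone genes had medians of 0.10 in LIF and -0.20 under Wnt3a and activin A.

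In LIF, fibroblast markers were higher in the KO, with 8 measured members between log2 fold changes of 0.18 and 1.04. KO replicate 3, in which Mir6236 held 28.6% of summed FPKM, is not the sole source, since the median was 0.57 without it against 0.53 with it. Carry-over of feeder fibroblasts stays open. A common factor of all markers was tested with a bound set before its value was known, and the Cochran Q p was 0.0282, and 0.0457 for the 5 markers below 5 FPKM in the controls. Leaving out 1 of these 5 moved that Cochran Q p between 0.0214 and 0.312. That bound was judged wrong after the values were seen, because carried-over RNA adds to what ES cells make themselves and needs no common factor: in the ES cell libraries, scaled separately, Col1a1 was at 8.82 FPKM against 1.33 FPKM in the LIF controls, but Pdgfrb at 1.35 against 1.28 FPKM.

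H3K79me2 peaks covered 2.21 times as much of the genome with 3-MB-PP1 as with DMSO. A more sensitive peak calling in the 3-MB-PP1 library, from depth or background, was tested with equal numbers of top-scoring peaks, where the ratio was 1.97 rather than near 1. Broad peaks also widen with depth, and 96.8% of DMSO peaks were found in the 3-MB-PP1 list as a more sensitive library would give, so depth and inhibition of Cdk1 cannot be told apart with 1 library each.

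A hypothesis was that KO cells lie further along the change that control cells undergo from LIF to Wnt3a and activin A. Across 13791 genes, which are not independent replicates, the KO effect under Wnt3a and activin A had a Pearson r of -0.465 and a Spearman rho of -0.509 with that change, the reverse of the hypothesis over all genes. Primitive streak genes went with the hypothesis. All 13 were at a higher level in control cells under differentiation, and 11 rose further in the KO (median 0.77). The comparison shares the control libraries, so unchanged groups simulated against them gave an r of -0.146, and the covariance was -0.318 against a simulated -0.0553. A shift common to the control libraries under Wnt3a and activin A would also give a negative r. Summed FPKM was higher in those libraries than in the KO libraries, so the comparison cannot decide the question. With the trend in span and level removed r was -0.338. Of 1638 genes that were at least 1 log2 unit higher in control cells under differentiation, 21.1% were higher in the KO. These genes were picked by the same control libraries, so their share has the same limit. The tables were scaled separately, which bears on the change but not on the KO effect.

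A second hypothesis was that Thio-ChIP sites lie at an end of H3K79me2 domains. Over the 678 Thio-ChIP peaks whose midpoint lay inside a DMSO peak, the median distance to the nearest edge was 0.0873 of the domain's width, against 0.229 to 0.276 in 100 random placements inside the same domains. This goes with a position near an edge for these 678 peaks. The rest of the 2852 Thio-ChIP peaks that met a DMSO peak had their midpoint outside it. By definition they crossed an edge of it, and they were not part of this comparison. The Thio-ChIP and H3K79me2 lists also come from cells treated differently, and were taken to use the same build, which was not checked for each list. Which edge lies at a gene start was not tested because peaks and genes were not joined.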
